A study of Mus musculus with 5 samples.

How the data were processed

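RNA from 5 samples of MIN6 cells was measured on 1-colour Agilent mouse expression arrays, 1 array per sample. MIN6 is an insulin-secreting line derived from a mouse insulinoma and is widely used as a model of pancreatic beta cells. The cells had received exosomes, the small extracellular vesicles that cells release, purified from muscle kept ex vivo. Per the labels, 2 samples received vesicles from muscle of mice on a standard diet (EXO-STD) and 3 samples received vesicles from muscle of mice on a high fat diet (EXO-HP). Per the labels' protocols, RNA was prepared with Trizol, its quality was monitored on a Bioanalyzer, and Cy3-labelled cRNA was made by linear amplification from 0.1 µg of RNA. The titles call the samples biological replicates without saying whether the cultures were separate or the vesicles came from separate mice, so p-values measure the spread between these samples only, part of which may be technical.

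The scanner tables hold spot intensity values that were extracted with Feature Extraction 10.7.3.1, per the file headers. The submitters' processing notes name Agilent Feature Extraction 9.1 and limma instead, and the role of limma is not given in the sources used here. The processed intensity of each spot is the Cy3 signal after background subtraction and detrending, with surrogate values for spots not above background, per the file headers. The values were not scaled between arrays. The deposited value table of the whole series holds log2 values. Its columns had the same distribution, with a median of 7.93 on each of the 5 arrays, and their ranks equalled those of the mean signal minus the median local background of the same array (Spearman rho = 1 on each array). The table thus matched background-corrected, quantile-normalised log2 values without centring of genes, and its direction was that of the scanner signals. All 5 of its columns were matched to samples, leaving 0 unmatched.

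Each array had 44397 spots, of which 43020 were not controls and carried 39429 probes. Log2 of the processed signal was taken, outlier spots were left out, spots of 1 probe were averaged, and each array's 75th percentile was subtracted. A normalised log2 signal of 0 is therefore the 75th percentile of an array. Probes with no usable spot on some array (110) and probes not well above background on at least 2 arrays of 1 group (7376) were left out, and 31943 probes were tested. No spot was saturated. Where a probe was not well above background on any array of a group, the fold is given as a bound. It sets the brighter group's mean against the dim group's mean of, per array, the higher of the probe's own signal and the lowest signal of any probe well above background there, and no fold is given where that bound was under 1. The bound holds for this processing only and carries no sampling error.

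Gene symbols came from the array tables. RefSeq accessions were updated through a table of RefSeq genes of assembly GRCm38.p6, used for names only, which named 26055 probes (66.1%) and changed the symbol of 3358. Probe positions are those of the array design on the mm9 build, per the file headers. For genes with several probes, the probe with the highest mean signal over all arrays stands for the gene, which gave 25918 genes, and disagreeing probes are given where a gene is named.

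Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, EXO-HP minus EXO-STD, no covariates) with Benjamini-Hochberg adjustment over the tested probes and a threshold of adjusted p 0.05. The fit had 3 residual and 2.59 prior degrees of freedom. A rank or permutation test of 2 against 3 arrays cannot go below a 2-sided exact p of 0.2. Lists of genes were tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the 29 lists with at least 5 tested members. The 30 lists, 21 of pathways and 9 of cell type markers, as well as the tests, the filter, the alternatives and the rule for named genes were fixed before the data were examined.

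The rule for named genes took, in each direction, 13 genes with 1 symbol outside multi-copy families whose EXO-HP arrays all lay on 1 side of both EXO-STD arrays. Those past the threshold came first by fold change, and the remaining places went to the smallest unadjusted p. Ins1, Ins2 and Ptch1 were named in every case, and so were 2 to 4 members with the smallest p of lists described by member. Gipr, Acta1, Ckm, Tnnc2 and, from a second oxygen list, Kdm3a and Narf fall outside that rule and were chosen after their values were seen.

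The fit was tested on simulated data, 10 sets of 31943 probes with the real means, spread and group sizes and 200 changed probes each, beside 20 genes shifted as a list. It recovered 0.2% of 2-fold, 25% of 4-fold, 70.2% of 8-fold and 85.4% of 16-fold changes at adjusted p 0.05, and of its 952 calls 47 were unchanged probes and 1 a gene of the shifted list. Camera, run on 25918 genes, found the list of 20 genes shifted by -0.4 in 10 of 10 sets, in simulations whose genes varied independently.

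The alternatives were normexp background correction (offset 50), quantile normalisation, median scaling, no filter on dim probes, a filter for all 5 arrays, slide as a fixed block or a random one (lists then by cameraPR), the slide with both groups alone, the replicate number as a block, an intensity trend, array weights, the deposited log2 table, leaving out each array, an unadjusted threshold with 1.5-fold, and, for lists, an estimated correlation and fry. Random lists matched on abundance (10000 per list, each member replaced by a gene within 100 ranks of mean signal) described where a list's median lay. Figures were drawn with matplotlib 3.10.9.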

Results

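The study asked which genes of beta cells respond to vesicles released by muscle of mice on a high fat diet. Gene expression was measured in MIN6 cells treated with EXO-STD vesicles (standard diet, n = 2 arrays) or EXO-HP vesicles (high fat diet, n = 3 arrays). EXO-STD replicates 1 and 2 and EXO-HP replicate 1 lay on slide 1 and in scan 1, whereas EXO-HP replicates 2 and 3 lay on slide 2 and in scan 2. The share of spots well above background was 73.4%, 71.8% and 74.0% on slide 1 and 91.6% and 81.6% on slide 2. Over the tested probes, the arrays correlated with Pearson's r between 0.969 and 0.986 across genes, which are not independent replicates. EXO-HP replicate 1 had r = 0.986 with each EXO-STD replicate, against 0.969 with EXO-HP replicate 2 and 0.981 with EXO-HP replicate 3. The EXO-STD replicates had r = 0.982 with each other, and EXO-HP replicates 2 and 3 had 0.979. The median standard error of a log2 fold change was 0.27, and the number of arrays limits the precision.

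Genes of glycolysis and of the response to low oxygen were lower as a group in cells that had received EXO-HP vesicles. Of the 19 tested members of this list, 17 were lower, with a median log2 fold change of -0.37 (camera, adjusted p = 1.58e-10), a call that was lost when the correlation between the genes was estimated from the data (p = 0.108, adjusted p = 0.649). Without EXO-STD replicate 1 the list's median was -0.12 (p = 0.316 with an estimated correlation). Ldha, the lactate dehydrogenase subunit that turns pyruvate into lactate, had a log2 fold change of -1.88 ± 0.61 (SE), a 3.67-fold lower mean. Bnip3, a mitochondrial protein induced by hypoxia, stood at -0.92 ± 0.27, and Slc16a3, the lactate exporter MCT4, at -1.28 ± 0.42. Without EXO-STD replicate 1 these were -0.95 for Ldha, -0.56 for Bnip3 and -0.68 for Slc16a3. The insulin genes and the list of beta cell identity genes did not pass their tests. No single gene could be called: with limma, 0 of 31943 probes passed adjusted p 0.05, and the smallest adjusted p was 0.807.

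At an unadjusted p under 0.05 there were 1797 probes, 5.63% of those tested against 5% by chance, of which 1721 were higher and 76 lower in EXO-HP. The groups did not overlap for 5712 probes (17.9%), against 20% by chance. The higher share of 95.8% was 74.6% with quantile normalisation, 84.2% with median scaling, which moved the median of all probes from 0.08 to -0.10, and 59.3% with slide as a fixed block. The higher probes were dim, with a median log2 processed signal of 5.49 against 8.90 for all tested probes. In the dimmest decile of probes, the median difference from EXO-STD was 0.23 on EXO-HP replicate 1, 1.52 on replicate 2 and 0.74 on replicate 3.

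**Figure D1:**
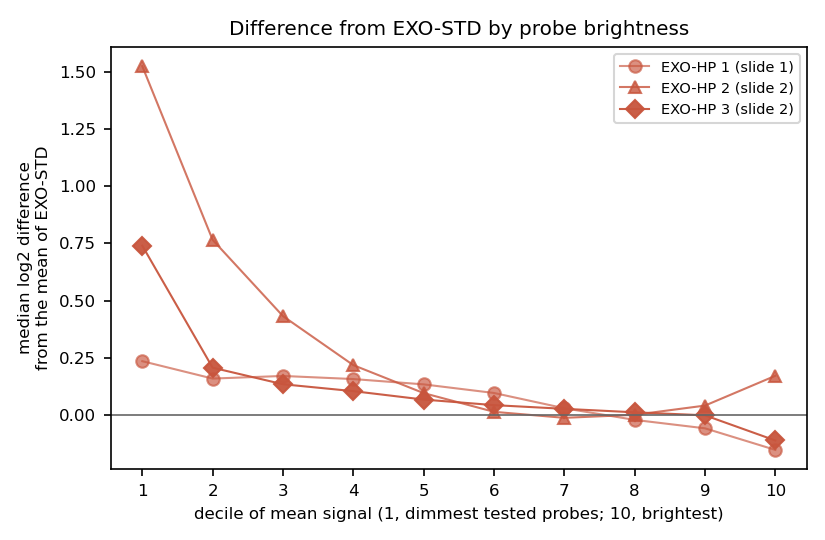
Median log2 difference of each EXO-HP array from the mean of the EXO-STD arrays (vertical axis) by decile of mean probe signal (horizontal axis, 1 dimmest, 10 brightest), with 1 line per array. In the first decile the lines stand at 0.23, 1.52 and 0.74 for EXO-HP replicates 1, 2 and 3, and in the seventh decile they lie between -0.01 and 0.03.

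The 13 genes named as higher were all near the detection limit. None was well above background on an EXO-STD array, so their folds are bounds, and none passed the threshold (adjusted p = 0.807 for each). Trim10, an erythroid RING finger protein, was at least 2.49-fold higher, Cysltr1, a receptor for cysteinyl leukotrienes, at least 1.77-fold and Mansc4 at least 1.64-fold. Foxf1, a mesenchymal forkhead factor, was at least 1.44-fold and Zfp651 at least 1.36-fold higher. With normexp the log2 fold changes were 0.46 for Trim10, 0.54 for Cysltr1, 0.39 for Mansc4, 0.26 for Foxf1 and 0.16 for Zfp651. These bounds therefore hold for the main processing only. Alox5, the 5-lipoxygenase that starts leukotriene synthesis, had a bound of 1.00, and Opn1sw, a cone opsin, and Gnat3, the taste transducin subunit, had bounds of 1.01. Reg2, Snai1, Amh, Lama4 and Tmem132e had no fold, because their mean in EXO-HP did not exceed the level that a signal well above background would have needed in EXO-STD. Trim10, Cysltr1, Mansc4 and Zfp651 were well above background on all 3 EXO-HP arrays, and the other 9 on 2 of them.

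The 13 genes named as lower were well above background on both EXO-STD arrays, and none passed the threshold (adjusted p of 0.807 or 0.879). Lox, the lysyl oxidase that crosslinks collagen, showed -2.35 ± 0.32 (SE), with means of -5.05 ± 0.06 (SD, n = 2) in EXO-STD and -7.40 ± 0.48 (SD, n = 3) in EXO-HP, where 1 of 3 arrays was well above background. Ak4, a mitochondrial adenylate kinase, went from -2.35 ± 0.67 (SD, n = 2) to -4.39 ± 0.26 (SD, n = 3), a log2 fold change of -2.04 ± 0.34. Slc26a5, known as prestin, had -2.57 ± 0.47. The 2 probes of Slc16a3 gave -1.42 and -1.28. Anp32a, an acidic nuclear phosphoprotein, had probes at -1.52 and -0.35. Sfrp2, a secreted Wnt antagonist, had -1.24 ± 0.31, Bdkrb2, the bradykinin B2 receptor, -0.98 ± 0.27, and Dync1i1, a dynein intermediate chain, -1.02 ± 0.29. Without EXO-STD replicate 2 the values were -0.99 for Anp32a, -0.79 for Sfrp2 and -0.64 for Bdkrb2, and with slide as a block Dync1i1 had -0.66. Pigt, a subunit of the GPI transamidase, had -0.81 ± 0.20, Fkbp11 -0.75 ± 0.24 and Dact2 -0.86 ± 0.29. With normexp the log2 fold changes were -0.50 for Lox, -1.10 for Slc26a5, -0.51 for Sfrp2, -0.28 for Bdkrb2 and -0.43 for Dync1i1. The sizes for these dim genes therefore hold for the main processing only. Among the brighter genes, normexp gave -1.48 for Ak4, -0.86 for Pigt, -1.50 for Anp32a, -0.54 for Fkbp11 and -0.77 for Dact2.

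Within the hypoxia and glycolysis list, no member passed adjusted over all probes or adjusted over the list alone (smallest adjusted p = 0.187), and 4 had an unadjusted p under 0.05. These were Ldha, Bnip3, Pfkfb3, which makes the activator of phosphofructokinase, at -0.71 ± 0.26, and Pdk1, a kinase that inhibits pyruvate dehydrogenase, at -0.71 ± 0.26. Without EXO-STD replicate 1, Pfkfb3 had -0.38 and Pdk1 -0.46. The 3 probes of Ldha ranged from -2.12 to -1.40, the 3 of Bnip3 from -1.07 to -0.37, and the 2 of Pfkfb3 from -0.71 to -0.22. Lox, Ak4 and Slc16a3, which the list does not hold, are also known to be induced by low oxygen.

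Relative to the mean of EXO-STD, the median of the hypoxia and glycolysis list was -0.43 on EXO-HP replicate 1, -0.20 on replicate 2 and -0.55 on replicate 3. The EXO-STD arrays themselves stood at 0.30 (replicate 1) and -0.30 (replicate 2), so that EXO-STD replicate 2 lay below EXO-HP replicate 2. On EXO-HP replicates 1, 2 and 3, respectively 14, 7 and 14 of the 19 members lay below both EXO-STD arrays. Ldha read 4.67 and 2.82 on EXO-STD replicates 1 and 2 and 1.30, 2.34 and 1.97 on EXO-HP replicates 1, 2 and 3. Without EXO-STD replicate 1, 13 of 19 members were lower, and without EXO-STD replicate 2 the list's median was -0.78. With slide as a block, which leaves the arrays of slide 1, the median was -0.43 with 18 of 19 members lower (p = 0.201 with an estimated correlation).

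**Figure D2:**
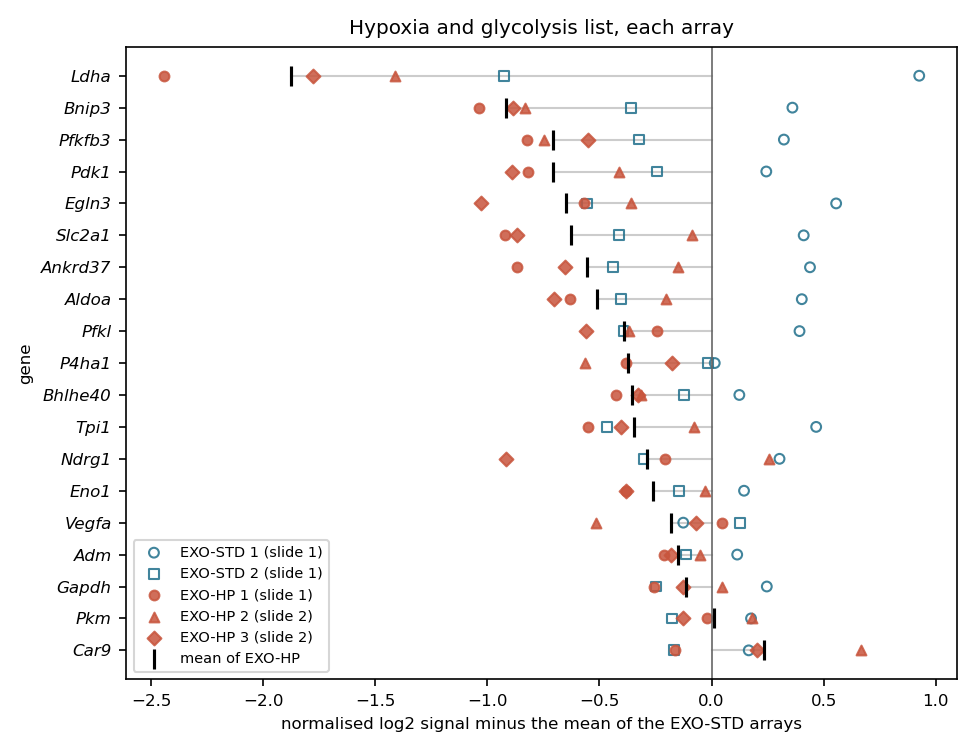
Normalised log2 signal of the 19 tested genes of the hypoxia and glycolysis list on each array, minus the mean of the EXO-STD arrays (horizontal axis), with 1 row per gene and the mean of the 3 EXO-HP arrays as a black bar. EXO-STD replicate 1 lies to the right of EXO-STD replicate 2 for 18 of the genes, and Ldha spans from 4.67 on that array to 1.30 on EXO-HP replicate 1 before subtraction.

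Ldha was measured by a probe at chromosome 7, 54110937 to 54110996, Bnip3 by that at chromosome 7, 146082760 to 146082819, and Slc16a3 by that at chromosome 11, 120820023 to 120820082 (mm9). The probe of Ak4 lay at chromosome 4, 101139464 to 101139523, and the probe of Lox at chromosome 18, 52680465 to 52680524. The array design assigns each to the transcript of the gene named. Exon annotation was not used here.

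The insulin genes, the brightest of the named genes, did not pass the test. Ins1 had 7.45 ± 0.03 (SD, n = 2) in EXO-STD and 7.59 ± 0.02 (SD, n = 3) in EXO-HP, a log2 fold change of 0.15 (95% interval -0.31 to 0.60, adjusted p = 1.00), which was -0.03 with median scaling. Ins2 had 7.40 ± 0.004 (SD, n = 2) in EXO-STD and 7.72 ± 0.03 (SD, n = 3) in EXO-HP. Its log2 fold change was 0.32 (95% interval -0.13 to 0.77, limma adjusted p = 0.968). The groups did not overlap for Ins1 or Ins2, as for 17.9% of all tested probes. The intervals use variances that limma moderates over all tested probes and are wider than these SDs alone would give. The beta cell identity list, which holds both genes beside transcription factors, glucose sensing and hormone processing, had 18 of 28 members higher, a median of 0.11 and adjusted p = 0.703. Its smallest p belonged to Pcsk1, a prohormone convertase, at 0.66 ± 0.32, followed by Ins2, Mafa, an insulin gene activator, at 0.38 ± 0.21, and Ucn3, a maturity marker, at 0.92 ± 0.52. Of 23 secretory granule and exocytosis genes, 15 were higher and 8 lower (median 0.05, adjusted p = 0.466), with the syntaxin Stx1a at 0.35 ± 0.21 and the Rab27 effector Sytl4 at 0.44 ± 0.28. Of 10 genes normally kept low in beta cells, 7 were higher and 3 lower (median 0.10, adjusted p = 0.703). Among them Ldha, at -1.88, and the lactate transporter Slc16a1, at 1.27 ± 0.55, went opposite ways, and neither passed. No member of these lists passed adjusted over all probes or adjusted over the list alone.

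Ptch1, the Hedgehog receptor, was measured by a pair of probes that disagreed. The brighter one, at chromosome 13, 63612879 to 63612938, gave 0.06 ± 0.18, with a 95% interval from -0.40 to 0.52, and turned to -0.12 with median scaling. The other, at chromosome 13, 63610298 to 63610357, gave -0.51 ± 0.26, with adjusted p = 1.00 for the first and 0.952 for the second. Of 14 Hedgehog pathway genes, 10 were higher and 4 lower (median 0.22, adjusted p = 0.466). Hhip, an inhibitor that binds Hedgehog ligands, was at least 2.71-fold higher from a level not well above background in EXO-STD. Its log2 fold change was 1.24 with quantile normalisation and 0.62 with normexp, so that bound holds for the main processing only. Gas1, a ligand co-receptor, had 1.03 ± 0.76 with a second probe at 1.76, and turned to -0.26 without EXO-STD replicate 2. Of 18 published targets of the miR-15/16 microRNA family, 11 were higher and 7 lower (median 0.04, adjusted p = 0.370), with the checkpoint kinase Chek1 at 0.52 ± 0.19 and the cyclin Ccne1 at 0.66 ± 0.32, whose 2 probes gave 0.66 and 0.13. No member passed adjusted over either list alone.

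Genes of proliferation were divided. Of 27 genes of G1/S and DNA replication, 13 were higher and 14 lower (median -0.03, adjusted p = 0.198), with the E cyclins on opposite sides, as Ccne2 had -0.57 ± 0.27. Of 28 genes of G2/M and mitosis, 16 were higher and 12 lower (median 0.03, adjusted p = 0.246). The mitotic kinase gene Aurkb had -0.56 ± 0.24 and Cdc20, the activator of the anaphase-promoting complex, 0.78 ± 0.37. None passed adjusted over either list alone.

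Genes of ribosomes and of mitochondrial respiration differed between arrays of the same group. The ribosomal protein list had 17 of 22 members lower, with a median of -0.05, and passed as a group (camera, adjusted p = 0.046; p = 0.499 with an estimated correlation). Rpl4 had -0.23 ± 0.20 and Rpl5 -0.29 ± 0.31. Relative to the mean of EXO-STD, its median was 0.38 on EXO-STD replicate 1 and 0.36 on EXO-HP replicate 2, against -0.38 on EXO-STD replicate 2, -0.26 on EXO-HP replicate 1 and -0.29 on EXO-HP replicate 3. Without EXO-STD replicate 1 the median was 0.28, and without EXO-STD replicate 2 it was -0.48. The group call was lost in 11 of 17 alternatives. The oxidative phosphorylation list, with 16 of 24 members lower (median -0.06, adjusted p = 0.054), stood at 0.32, -0.32, -0.32, 0.27 and -0.24 on the same arrays in the order EXO-STD 1 and 2 and EXO-HP 1, 2 and 3. Its smallest p values belonged to Sdhd, a subunit of succinate dehydrogenase, at -0.38 ± 0.22, and Cycs, cytochrome c, at -0.20 ± 0.26, whose 3 probes ranged from -0.20 to 0.21. With slide as a block the medians were -0.26 for ribosomal proteins and -0.32 for oxidative phosphorylation, and both lists passed (p = 0.467 and p = 0.389 with an estimated correlation). Over 17 alternatives the adjusted p of oxidative phosphorylation ranged from 3.34e-06 to 0.774, and that of ribosomal proteins from 1.10e-07 to 0.706.

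The remaining pathway lists did not pass. The unfolded protein and integrated stress response list had 9 of 23 members higher (median -0.04, adjusted p = 0.202), with the chaperone Hyou1 at 0.20 ± 0.23 and Creld2 at 0.27 ± 0.24. Of cholesterol synthesis genes, 15 of 25 were higher (median 0.04, adjusted p = 0.562), with Acat2 at 0.32 ± 0.22 and Insig1 at 0.21 ± 0.18. Fatty acid synthesis genes had 6 of 13 higher (median -0.00, adjusted p = 0.370), and fatty acid oxidation and PPAR targets 11 of 20 (median 0.08, adjusted p = 0.473). For the oxidative stress response, 6 of 16 were higher (median -0.01, adjusted p = 0.264). NF-kappaB and inflammation genes had 9 of 15 higher (median 0.09, adjusted p = 0.940). In the interferon response list, 11 of 21 were higher (median 0.04, adjusted p = 0.490), with Ifit3 at -0.35 ± 0.22 and Oasl2 at 0.29 ± 0.20. Among p53 targets and apoptosis genes, 9 of 17 were higher (median 0.02, adjusted p = 0.246), with Gadd45a at -0.30 ± 0.20 and Bid at 0.45 ± 0.32. Immediate early genes had 8 of 18 higher (median -0.01, adjusted p = 0.250), with Junb at 0.58 ± 0.26 and Egr1 at -0.36 ± 0.22.

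Of 20 genes of vesicle and endosome machinery, 7 were higher (median -0.03, adjusted p = 0.202). Chmp4b, an ESCRT-III subunit, had 0.98 ± 0.30, though its 3 probes ranged from 0.28 to 0.98, and Tsg101, an ESCRT-I subunit, had -0.32 ± 0.19. Of 17 extracellular matrix and TGF-beta target genes, 10 were higher (median 0.02, adjusted p = 0.466). Lox was the only member of the 30 lists that passed adjusted over the list alone (adjusted p = 0.008), which does not adjust for the search over 30 lists. Over all probes its limma adjusted p was 0.807, and with normexp its log2 fold change was -0.50. Col4a2, a collagen IV chain, was at least 1.47-fold higher from a level not well above background in EXO-STD. With slide as a block, the median changed sign in 8 of the 29 tested lists (genes normally low in beta cells, miR-15/16 targets, fatty acid synthesis, fatty acid oxidation, NF-kappaB and inflammation, p53 targets, extracellular matrix, and fibroblast). In 10 of the 29 tested lists the median lay above 0 while camera's direction was downward; camera sets a list against the other genes rather than against 0. Median and mean had opposite signs in 5 lists (fatty acid synthesis, immediate early genes, vesicle and endosome machinery, adipocyte and pancreatic duct).

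**Figure D3:**
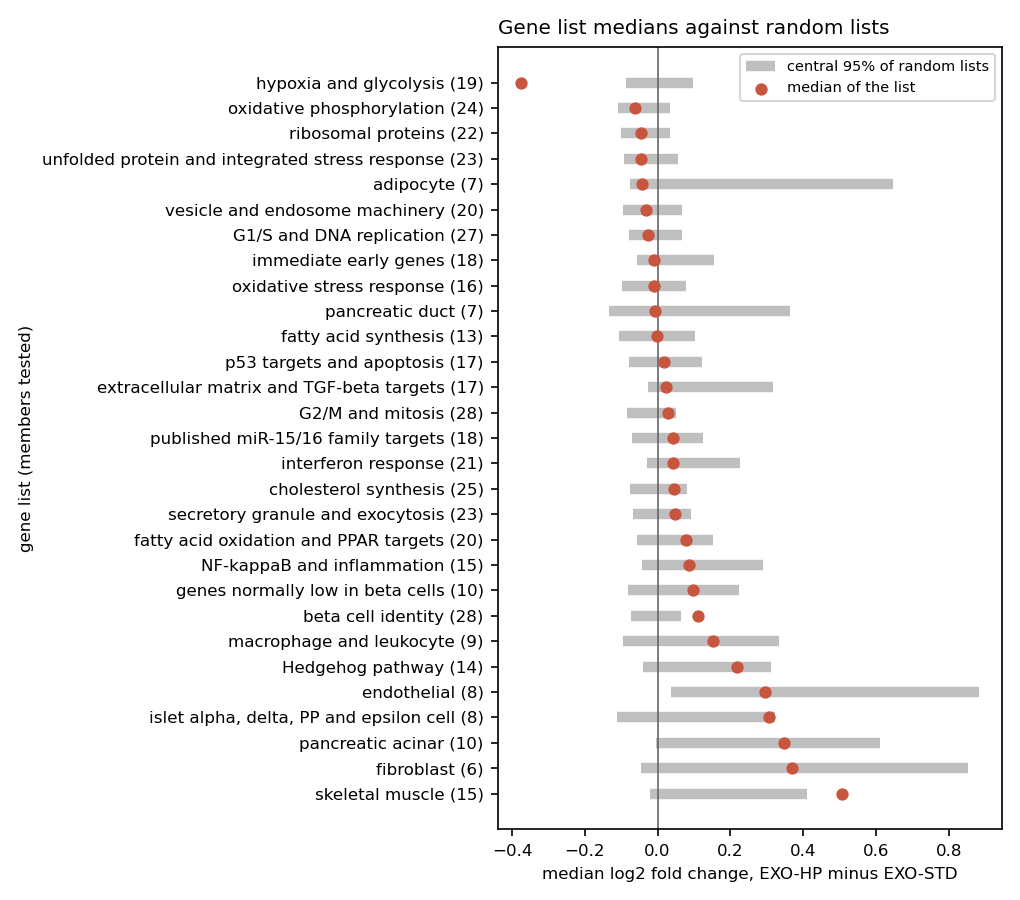
Median log2 fold change of each of the 29 tested lists (points, horizontal axis) with the number of tested members in brackets, and the central 95% of the medians of 10000 random lists matched on abundance (grey bars). The hypoxia and glycolysis list, at -0.37, lies outside its bar from -0.09 to 0.10, beta cell identity at 0.11 outside one from -0.07 to 0.06, and skeletal muscle at 0.51 outside one from -0.02 to 0.41.

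Skeletal muscle markers had 15 of 15 tested members higher in EXO-HP, with a median of 0.51 and adjusted p = 0.054 (p = 0.207 with an estimated correlation), and so missed the threshold. Mylpf, a fast myosin light chain, was at least 1.67-fold higher from a level not well above background in EXO-STD. Its log2 fold change was 0.47 with quantile normalisation and 0.25 with normexp, so that bound holds for the main processing only. The calcium pump Atp2a1 had 0.51 ± 0.20, Actn3, the actinin of fast fibres, 0.46 ± 0.22, and the fast troponin T gene Tnnt3 0.92 ± 0.57, with probes at 0.92 and 2.09. None passed adjusted over the list alone (smallest adjusted p = 0.054). The list's median relative to EXO-STD was 1.09 on EXO-HP replicate 1, 0.44 on replicate 2 and 0.10 on replicate 3. With slide as a block it was 1.09 and the list passed (adjusted p = 6.47e-08), a call that was lost with an estimated correlation (adjusted p = 0.85, p = 0.0487 before adjustment). Over 17 alternatives the adjusted p ranged from 3.54e-12 to 0.672, and it was 0.672 without EXO-HP replicate 1, where the median was 0.33.

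**Figure D4:**
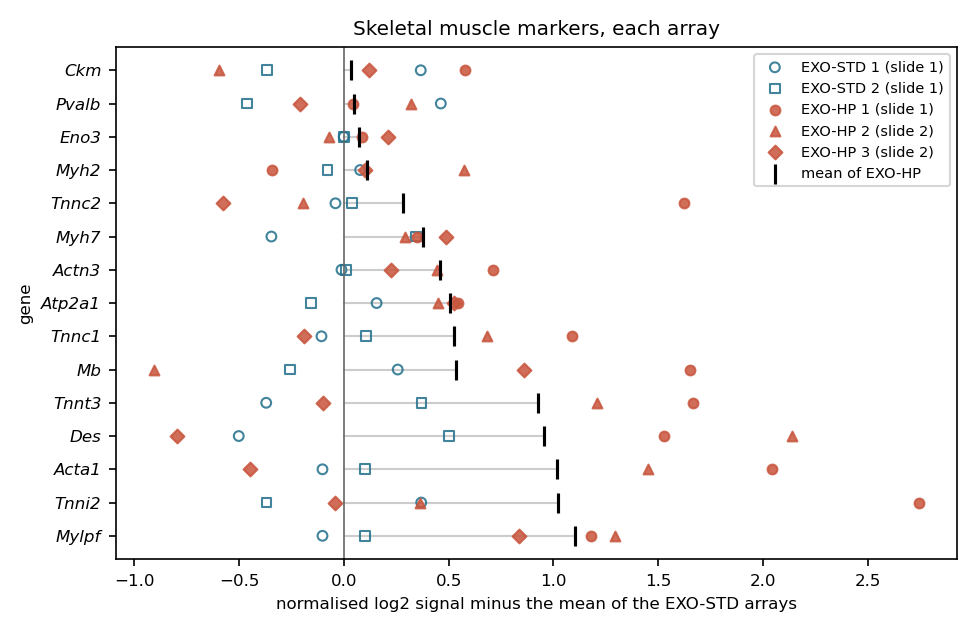
Normalised log2 signal of the 15 tested skeletal muscle markers on each array, minus the mean of the EXO-STD arrays (horizontal axis), with 1 row per gene and the mean of the 3 EXO-HP arrays as a black bar. EXO-HP replicate 1 was the highest of the 5 arrays for 9 of the 15 genes.

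Markers of other cell types did not pass. Macrophage and leukocyte markers had 8 of 9 higher (median 0.15, adjusted p = 0.272), with Cd14 at 0.56 ± 0.19 and C1qb at 0.98 ± 0.37. Pancreatic acinar markers had 9 of 10 higher (median 0.35, adjusted p = 0.246), with the amylase Amy2a5 at least 1.40-fold higher and Rnase1 at 1.04 ± 0.45; the list passed in 3 of 17 alternatives, over which adjusted p ranged from 0.0035 to 0.673. Markers of islet alpha, delta, PP and epsilon cells had 6 of 8 higher (median 0.31, adjusted p = 0.250), with the alpha cell factor Irx1 at least 2.43-fold higher and somatostatin, Sst, at 0.52 ± 0.22. Fibroblast markers had 5 of 6 higher (median 0.37, adjusted p = 0.250; -0.014 with slide as a block), endothelial markers 5 of 8 (median 0.30, adjusted p = 0.466), adipocyte markers 3 of 7 (median -0.04, adjusted p = 0.918; Lep 1.12 ± 0.43 and Plin1 0.42 ± 0.24) and pancreatic duct markers 3 of 7 (median -0.01, adjusted p = 0.338). Random lists matched on abundance had medians of 0.33 for fibroblast, 0.35 for endothelial, 0.24 for acinar and 0.09 for macrophage and leukocyte markers. The measured medians lay at percentiles 56.7, 39.8, 76.5 and 69.9, respectively, so they were usual for genes of similar abundance. The islet, adipocyte and duct lists had random medians of 0.07, 0.22 and 0.07 and lay at percentiles 97.1, 3.93 and 24.9. With slide as a block, C1qb had 0.30, Rnase1 0.34, Lep 0.46 and Plin1 0.25. Amy2a5 had a log2 fold change of 0.25 with quantile normalisation and 0.19 with normexp, and Irx1 had 1.12 and 0.45. The bounds of Amy2a5 and Irx1 therefore hold for the main processing only. On EXO-HP replicate 2, the median difference from EXO-STD was 1.10 for acinar, 0.92 for fibroblast, 0.77 for endothelial and 0.69 for macrophage and leukocyte markers, the largest of the 5 arrays for each. With genes dim on all arrays of a group set to their bound, the medians of 4 lists changed, to 0.19 for acinar, 0.00 for endothelial, 0.04 for NF-kappaB and inflammation and 0.00 for p53 targets. Only 2 of 5 erythroid markers were measured, 1 higher and 1 lower, too few to test.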

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

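Each alternative below was planned. Across 79 named genes and 1320 values under alternatives, 1297 kept their direction and their side of the threshold. Another 20 changed sign, and 3 passed the threshold, namely Cysltr1 (2.87), Lox (-2.86) and Slc26a5 (-3.17), each on the slide with both groups alone, which leaves 1 residual degree of freedom. Much of the count of 1297 was fixed in advance. The 13 genes named in each direction had EXO-HP arrays on 1 side of both EXO-STD arrays, so leaving out an array could not turn their sign. The changes of filter and the intensity trend moved 0 genes, and no gene was near the threshold in the main fit (limma, smallest adjusted p = 0.807). The log2 fold change moved by over 1.5 times or changed sign in 39 of the 79 genes when some array was left out (24 without EXO-STD replicate 1 and 22 without EXO-STD replicate 2), in 25 with slide as a fixed block, in 43 with normexp, in 24 with quantile normalisation, in 25 with median scaling and in 41 in the deposited table. The hypoxia and glycolysis list kept its direction in every alternative run. It stayed past the threshold in the 17 that used camera's preset correlation, with adjusted p from 2.33e-13 to 0.0376, and lost it with an estimated correlation (median -0.37, adjusted p = 0.649) and with fry (median -0.37, adjusted p = 0.951). With limma, the count of probes at adjusted p 0.05 was 0, with 631 to 3412 probes at unadjusted p under 0.05, under each alternative with 2 exceptions. It was 94 (57 higher) on the slide with both groups alone, and 3 without EXO-STD replicate 1, for a range over the left-out arrays of 0 to 3. At an unadjusted p under 0.05 with at least 1.5-fold, 1700 probes were counted. Where an array was left out so that EXO-STD kept 1, that array was assumed to vary like the EXO-HP arrays.

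The count of lists past the threshold was 2 in the reported analysis. It was also 2 with median scaling, with no filter on dim probes and with the filter for all 5 arrays, but with skeletal muscle in the place of ribosomal proteins. The acinar list passed on the slide with both groups alone, with a replicate block and without EXO-HP replicate 3, and the oxidative stress list without EXO-STD replicate 2. The count was 1 with normexp background correction, quantile normalisation, slide as a random block and the deposited log2 table. It was 4 with slide as a fixed block and with an intensity trend, 5 on the slide with both groups alone, and 0 with an estimated correlation and with fry, and it ranged from 1 (without EXO-STD replicate 1) to 4 (without EXO-STD replicate 2) over the left-out arrays. Ptch1 turned to -0.021 with normexp, -0.064 with quantile normalisation, -0.12 with median scaling and -0.12 in the deposited table, and Ins1 to -0.030 with median scaling and -0.034 in the deposited table. Ckm turned to -0.068 with normexp, -0.64 with quantile normalisation, -0.14 with median scaling, -0.042 with slide as a random block, -0.0095 with a replicate block and -0.29 in the deposited table, and Tnnc2 to -0.15 with array weights. Over the left-out arrays, the values ranged from -0.33 to 0.40 for Ckm, -0.38 to 0.71 for Tnnc2, -0.47 to 9.67 for Gipr, -0.26 to 2.32 for Gas1, -0.43 to 0.028 for Cycs and -0.48 to 0.28 for the median of the ribosomal protein list, which was 0.059 with a replicate block. The cause of these changes was not tested. The replicate block left 0 probes at adjusted p 0.05 and 1663 at unadjusted p under 0.05, against 1797; the numbers were shared by 2 pairs of arrays only and did not pair them (correlations of deviations 0.02 and -0.06). Signal over background limits the dim probes, as 26951 of the 31943 tested probes were well above background on all 5 arrays.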

Other observations

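Chosen only after the result was seen were the tests of slide or scan for all 3 patterns below, of EXO-STD replicate 1 alone, of the other splits of the arrays, and of the 4 muscle transcripts. The slide block and the leaving out of each array were planned as alternatives, and only their use to weigh these explanations was chosen later. A second list of 23 genes regulated by oxygen, drawn up after the hypoxia and glycolysis list was seen but before its own values were, had 16 of its 21 tested members lower in EXO-HP, with a median of -0.29 (p = 0.0232 with an estimated correlation, not adjusted). Of its members, Ak4 and Slc16a3 had an unadjusted p under 0.05 (0 passed the threshold with limma). Both are also among the 13 genes named as lower from the same fit, so the second list may not have been blind to them. Kdm3a, a histone demethylase, had -0.43 ± 0.21, and Narf -0.35 ± 0.19. Without EXO-STD replicate 1 the median of this list was -0.10.

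The median of the beta cell identity list, 0.11, lay at percentile 99.97 of random lists matched on abundance, although its test did not pass. Gipr, the receptor for the incretin GIP and a member of that list, read -8.58 on EXO-STD replicate 1 against 1.56 on EXO-STD replicate 2 and 1.68, 0.58 and 1.00 on the EXO-HP replicates. The medians of the adipocyte list and of the islet alpha, delta, PP and epsilon cell list lay at percentiles 3.93 and 97.1. EXO-STD replicate 1 with EXO-HP replicate 2, set against the other arrays, gave 6662 probes at unadjusted p under 0.05, against 1797 for the real groups. After quantile normalisation the counts were 6174 and 867, respectively. With limma, 0 probes passed adjusted p 0.05 for either grouping. The larger counts point to a structure of the samples that crosses the groups. The arrays of slide 2 set against those of slide 1 gave 908 probes at adjusted p 0.05.

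The lower hypoxia and glycolysis list may be part of a wider difference in oxygen-regulated genes, as the second list's median also lay at percentile 0 of matched random lists, which does not separate the vesicles from a single array as its source. A shift shared by all genes of similar abundance is argued against by the list's own median, also at percentile 0. The random lists drew their genes independently, unlike the correlated genes of this list (estimated correlation 0.55), so the percentile is not a p-value. Slide or scan stays open, because the median of -0.43 within slide 1 rests on 1 EXO-HP array, and so does EXO-STD replicate 1 alone, as the median without it was -0.12 (p = 0.316 with an estimated correlation). Of the 10 splits of the arrays, 1, the real one, gave a camera p as small (-log10 p of 11.3, against 7.42 for the highest other), and 10 splits are too few for a share under 0.05. Camera p was 3.8e-08 to 0.000998 where 2 EXO-HP arrays, or EXO-STD replicate 1 and an EXO-HP array, formed the pair. It was 0.056 to 0.355 where EXO-STD replicate 2 and an EXO-HP array did. The estimated correlation between the list's genes was 0.55 against the preset 0.01, so a small preset p does not by itself mark the real grouping. The median of -0.37 was exceeded in size by 2 other splits, as the list's median was 0.44 for the rest minus EXO-HP replicates 1 and 3 and -0.46 for the rest minus EXO-STD replicate 1 and EXO-HP replicate 2.

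The excess of higher over lower probes at unadjusted p under 0.05 kept its direction with normexp, where the higher share was 93.6%. Both background treatments start from the same spot intensities and used the same scaling, so this bears on the choice between them only. The higher share was 74.6% with quantile normalisation and 73.2% in the deposited table. The size of the excess did move with processing. There were 1032 higher and 70 lower probes with normexp and 462 and 169 in the deposited table, against 1721 and 76 in the main fit. The share cannot say how much of the size comes from the background treatment. The higher share was 86.8% without EXO-HP replicate 2, which argues against that array as the whole source. With slide as a fixed block the share was 59.3%, near an even split, so a difference between slides or scans is a candidate explanation. That estimate rests on the 3 arrays of slide 1. No biological explanation was tested.

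The skeletal muscle list did not pass its test (adjusted p = 0.054; over 17 alternatives it ranged from 3.54e-12 on slide 1 alone to 0.672 without EXO-HP replicate 1), so the higher values of its 15 members are a pattern and not a call. A shift of all dim genes as its whole source is argued against by the list's median, at percentile 99.4 of random lists matched on abundance. Those lists had a median of 0.16 and drew their genes independently, whereas the estimated correlation between the markers was 0.15. The list's median was 0.20 with quantile normalisation and 0.23 with normexp, so such a shift is not excluded as a part of it. Slide or scan stays open, since the median within slide 1 was 1.09 but on 1 EXO-HP array. Muscle RNA carried in with the vesicles also stays open: over Acta1, Ckm, Mylpf and Tnnc2, abundant in muscle, the median was 0.65, but Acta1 had 1.01 ± 0.73, Tnnc2 0.28 ± 0.67 and Ckm 0.03 ± 0.42, which turned negative with normexp, quantile normalisation and median scaling. A response of the MIN6 cells to the donors' diet might also raise these markers, and the data hold no test of it.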
